A study of Mus musculus with 2 samples.

How the data were processed

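The authors deposited, for each of the 2 libraries, a sparse matrix of UMI counts per gene and cell barcode with its gene and barcode lists, without normalization. Per the submitters' processing notes the counts were made with Cell Ranger 2.2.0 against GRCm38/mm10. The annotation release, the calling of cells and the use of strand in counting are not given in the sources used here. The fewest UMIs of a barcode were 1987 and 2155, so lower barcodes were not used here, and free RNA was not estimated from empty droplets. Raw reads were not used here. Gene positions and strands were taken from GENCODE M21, which held 28416 of the 28692 gene identifiers of the files (99.0%).

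Cells were kept with at least 500 genes and at most 20% of UMIs from mitochondrial genes, which removed 163 barcodes from each library. Doublets were scored with Scrublet per library, and the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes, 95 and 115 cells. Scrublet's own threshold would have called 7 and 11. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen from the rankings within each library, without mitochondrial genes, Xist, Tsix and Y-linked genes. Genes seen in fewer than 3 cells were left out of clustering. The first 30 principal components and 15 nearest neighbours were clustered with the Leiden algorithm at resolution 1, with no integration of the libraries. Clusters were named after marker lists fixed beforehand, by the class with most markers among the 10 leading genes. Where no class had a marker among them, the class whose markers were found in most cells on average was taken. Most neuron-like clusters were named in this second way. In both cases at least 3 markers of the class had to be found in 25% or more of the cells. A cluster was left unnamed where the markers of another lineage were found in 60% of cells on average, where another lineage held 3 or more of the leading genes or more of them than the best class, or where cells were shallow and no own marker led. The limits for leaving a cluster unnamed were set after the clusters were seen, and they concern 2.42% and 2.70% of cells. Classes are called "-like" because they rest on these markers alone.

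Within neuron-like clusters a cell was inhibitory with 1 or more UMIs of Slc32a1 and none of Slc17a6, and excitatory in the reverse case. Cells with both or neither were counted and left out of the tests. Hcrt-high and Pmch-high neurons had 0.3% or more of their UMIs from Hcrt or Pmch, and were compared with excitatory neurons below 0.3% for both. These sorting genes were not read as findings. Counts were summed per library and group, each sum over at least 10 cells. Each comparison used edgeR's quasi-likelihood test on 4 sums with the library as a block, which leaves 1 residual degree of freedom, after filterByExpr and TMM normalization. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number at 2-fold or more was counted as well. The biological coefficient of variation was taken after the library block. It was 2.36% for inhibitory against excitatory, 5.94% for Hcrt-high, 3.23% for Pmch-high and 5.82% for the direct comparison. It describes how far the group difference varied between 2 pools of animals, and not the spread between animals or between pools. Tests at so few degrees of freedom lean on the spread shared by all genes. The prior degrees of freedom that edgeR gave to it were 92.7 for inhibitory against excitatory neurons and 11.8 for Pmch-high neurons. They were infinite for Hcrt-high neurons and for the direct comparison, so a gene's own spread did not enter there. All tests are 2-sided.

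A self-test put 200 changed genes into simulated sums of the same sizes, 50 at each of 4 folds. At 1.5-fold, 2-fold, 4-fold and 8-fold, 80%, 90%, 96% and 98% were called for inhibitory against excitatory neurons, and 34%, 64%, 92% and 94% for Hcrt-high neurons. For Pmch-high neurons these were 28%, 66%, 82% and 86%, and for the direct comparison 32%, 68%, 100% and 94%. Of the unchanged genes 7, 1, 0 and 10 were called in the 4 comparisons. Every gene was simulated with 1 common dispersion, whereas the inhibitory against excitatory and the Pmch-high test also fit a spread per gene. In the data, the Hcrt-high test and the direct comparison used the shared spread alone. Far fewer genes were changed than were called in the data. Recovery and false calls hold for that setting alone, and do not show how many calls in the data are true.

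A library's own fold was computed from CPM with 0.5 counts added to each arm. A fold against a group at 0 UMIs in both libraries is a lower bound against 3 counts over the group, and with 1 to 3 UMIs in the group the ratio is given with its exact 95% interval. Shares of cells have exact Clopper-Pearson and counts exact Poisson 95% intervals.

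With 1 library per sex label, no test between the labels was possible. CPM of summed counts were compared within classes of at least 50 cells in each library, by a rule of size (2-fold, 50 CPM and 50 UMIs in the higher library), and a gene that met it in one direction in at least 3 classes was called library-wide. The median log2 ratio of each gene list, over genes at 5 CPM or more, was placed among 10000 random lists matched in 20 bins of expression. These percentiles describe position and are not tests, since genes are not independent.

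The 18 gene lists, the sorting rules, the tests, the thresholds and the alternatives were fixed before the data were examined, as was the rule for the genes named. For each tested comparison these are the 8 highest and 8 lowest log2 fold changes among called genes with at least 50 CPM in the higher group of both libraries and 1 direction in both, leaving out sorting genes, Gm and Rik gene models and mitochondrial genes. From each list up to 4 called members with the largest change and up to 2 uncalled members with the highest CPM were added, and of these the text gives examples in order of size, chosen after their values were seen. A few genes that this rule names are not reported here. Cells were thinned at random to 3000 UMIs for shares of cells with a UMI, with 1500 UMIs and no thinning beside it.

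The alternatives for the tests were DESeq2 with its size factors, no filter on low counts, no library block, a cell filter of 1000 genes and 10%, no doublet removal, and either library alone. For inhibitory against excitatory neurons they were also a gate of 2 UMIs, thinning to 3000 UMIs and groups taken from clusters, and for the peptide groups a gate of 0.1% and of 1%. For class shares and values by label they were the 2 doublet alternatives, the stricter cell filter, Leiden resolutions of 0.5 and 2, a rule of 1.5-fold or 20 CPM, and CPM without mitochondrial and early response genes in the total. Chosen after seeing the data were the tests without neurons with 1% or more of their UMIs in the myelin list, the test without Hcrt-high and Pmch-high neurons, the shares at 5000 UMIs in the peptide groups, the counts of Oxt, hemoglobin, Opalin and Ermn UMIs in single cells, and the shares of Ptgds. The work used Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.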

Results

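Single-cell transcriptomes of the lateral hypothalamic area, a region whose neurons are known for their part in feeding, arousal and motivated behaviour, were measured in C57BL/6 mice at postnatal day 30. The assay was droplet 3' sequencing (10x Genomics Chromium, v2 chemistry), in which each captured transcript is counted through its unique molecular identifier (UMI). There were 2 libraries, each made from pooled littermates: 1 labelled male, from 3 animals, and 1 labelled female, from 2 animals. The library labelled male held 3439 barcodes and 23151801 UMIs, with a median of 5718 UMIs and 2619 genes per barcode. The library labelled female held 3793 barcodes and 27437142 UMIs, with a median of 6289 UMIs and 2867 genes. After filtering, 3187 and 3516 cells remained. The design asks which cell classes and neuron types make up this region, how they differ in gene expression, and whether the sexes differ. Wherever a pair of values is given for the libraries, the library labelled male comes first.

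The sex-linked genes went against both labels. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, - strand), the transcript that silences an X chromosome in female cells, had 19564 UMIs in 3024 cells of the library labelled male, or 895 CPM, its count scaled to a common total per library (95% Poisson interval 882 to 907). In the library labelled female it had 30 UMIs in 4 cells, a ratio of 770 (539 to 1141). No UMI of the 4 Y-linked genes was counted in the library labelled male. In the library labelled female, Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629, - strand) had 4281 UMIs and was found in 60.7% of cells, and Eif2s3y, Kdm5d and Uty had 1410, 863 and 623 UMIs. Against a floor of 3 counts in the library labelled male, these 4 genes were at least 1209-fold, 398-fold, 244-fold and 176-fold higher in the library labelled female. Over all barcodes, 92.8% of the library labelled male held Xist without a Y-linked UMI, and 77.2% of the library labelled female held a Y-linked UMI without Xist. The X-linked genes that escape silencing were also higher in the library labelled male: Eif2s3x by 1.62-fold (1.54 to 1.70), Ddx3x by 1.43-fold (1.38 to 1.48), Kdm5c by 1.35-fold (1.22 to 1.5) and Kdm6a by 1.16-fold (1.02 to 1.31). Tsix had 54 and 13 UMIs, but it lies antisense to Xist, and without a stated use of strand in counting its reads cannot be separated from those of Xist. Gene positions are those of GENCODE M21 on GRCm38. Each library is named by its label throughout, and every direction between the libraries is a direction between labels. These intervals, and those of all shares and ratios of UMIs, cover counting error only.

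**Figure D1:**
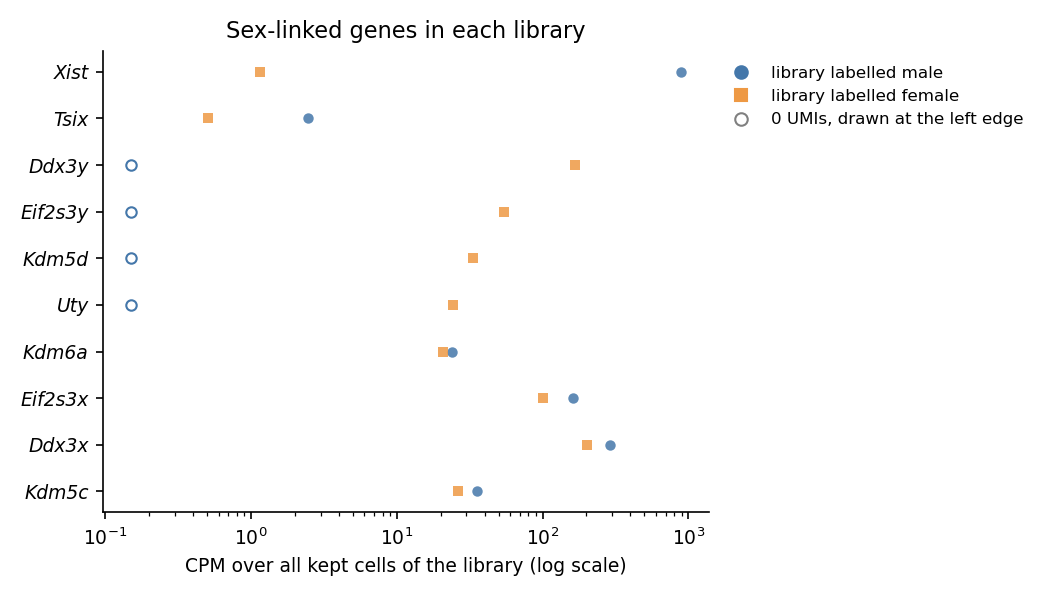
CPM of sex-linked genes over all kept cells of each library, on a log axis, with 1 point per library and open points at the left edge for 0 UMIs. Xist was high in the library labelled male, and the Y-linked genes were found in the library labelled female alone.

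Neurons made up most of both libraries. Neuron-like clusters held 63.9% (95% Clopper-Pearson interval 62.2 to 65.6) and 64.5% (62.9 to 66.1) of cells, and mature oligodendrocyte-like cells 19.1% (17.8 to 20.5) and 16.9% (15.6 to 18.1). Astrocyte-like cells made up 3.70% (3.07 to 4.42) and 5.20% (4.49 to 5.99), and microglia-like cells 2.29% (1.80 to 2.87) and 1.14% (0.814 to 1.55). The intervals of these 2 classes did not overlap between the libraries, which have no replicate. With the stricter cell filter astrocyte-like cells made up 1.12% (0.713 to 1.68) and 0.856% (0.50 to 1.37), so their direction turned and the intervals overlapped. Oligodendrocyte precursor-like cells made up 2.64% and 2.87%, newly formed oligodendrocyte-like cells 2.32% and 2.96%, endothelial-like cells 2.54% and 1.96%, fibroblast-like cells 0.722% and 0.910%, and mural-like cells 0.345% (0.172 to 0.617) and 0.910% (0.623 to 1.28), whose intervals overlapped without doublet removal. Of the 28 clusters, 14 were neuron-like and 2, with 2.42% and 2.70% of cells, were left unnamed because their leading genes were those of several classes. One of these was led by mural and hemoglobin genes and had endothelial markers in 90.0% of cells on average. The other had oligodendrocyte markers in 98.2% and astrocyte markers in 75.9% of cells on average. No cluster was named after ependymal cells, tanycytes, leukocytes, choroid plexus or dividing cells, and 0 cells so named allow a share of up to 0.0941% and 0.0853% of cells that the clustering would name. The lack of a cluster does not show that such cells were absent. Perivascular macrophages and erythrocytes had no cluster of their own either, but at resolution 2 clusters of 13 and 11 perivascular macrophage-like cells (0.408% and 0.313%) and of 1 and 5 erythrocyte-like cells appeared.

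**Figure D2:**
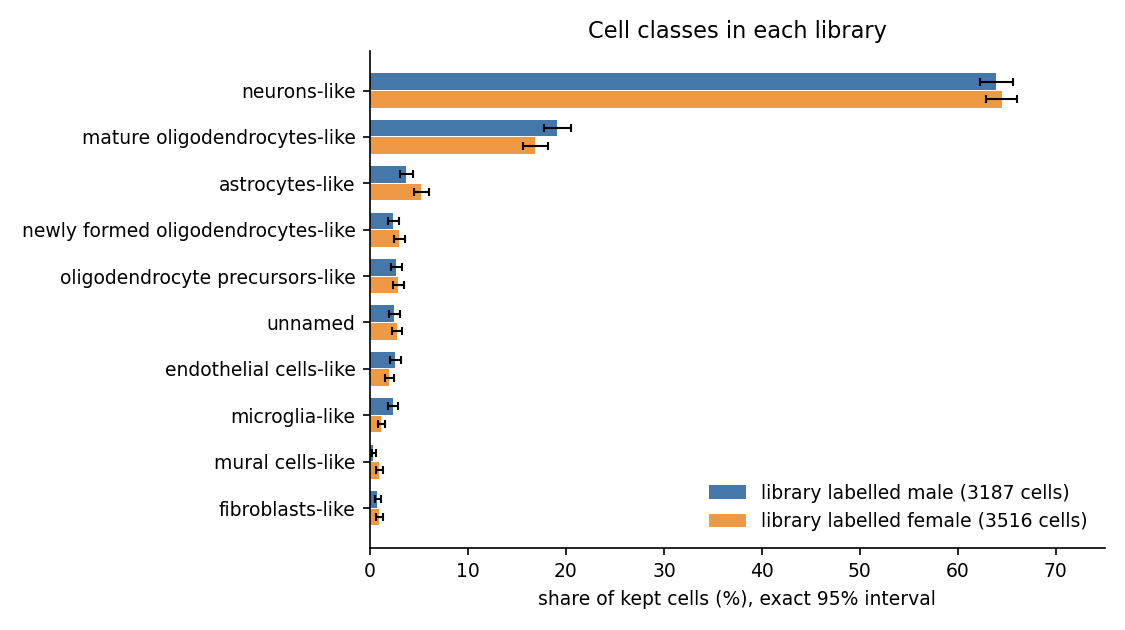
Share of kept cells, in percent, of each class, and of unnamed clusters, in the library labelled male and the library labelled female, with 95% Clopper-Pearson intervals as bars. Neuron-like cells made up 63.9% and 64.5%.

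Inhibitory neurons outnumbered excitatory neurons. Neuron-like cells were sorted by 2 vesicular transporter genes: Slc32a1, which loads GABA, and Slc17a6, which loads glutamate. Slc32a1 alone was counted in 984 (48.3%) and 1111 (49.0%) neurons, and Slc17a6 alone in 711 (34.9%) and 785 (34.6%). Both were counted in 112 (5.50%) and 146 (6.44%), and neither in 230 (11.3%) and 225 (9.93%). In the shallower mature oligodendrocyte-like cells, as background, Slc32a1 was found in 3.12% and 5.73% and Slc17a6 in 2.13% and 3.54%. Neurons with at least 0.3% of their UMIs from Hcrt, which encodes the arousal peptide hypocretin (orexin), numbered 82 (4.03%) and 84 (3.71%). Those with at least 0.3% from Pmch, which encodes melanin-concentrating hormone, numbered 85 (4.17%) and 61 (2.69%). No neuron reached both levels. These 2 groups were not sorted by the transporters: Slc17a6 alone was counted in 62 and 62 Hcrt-high and 48 and 35 Pmch-high neurons. Neither transporter was counted in 14 and 12 Hcrt-high and 26 and 16 Pmch-high neurons, and both in 5 and 8 and in 10 and 9. The other excitatory neurons hold no Slc32a1 UMI by definition. Between 0.1% and 1% of UMIs lay 36 and 21 neurons for Hcrt and 47 and 30 for Pmch, against 61 and 71 above 1% for Hcrt and 79 and 53 for Pmch, so the groups depend in part on where the limit is set. Hcrt-high neurons had a median of 16381 and 18305 UMIs and Pmch-high neurons of 14237 and 12947, against 7853 and 8097 in the other excitatory neurons.

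Among the genes that differed most between inhibitory and excitatory neurons were transcription factors of their lineages and neuropeptides. In inhibitory neurons Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981, + strand), a homeobox factor of GABA neuron development, was 41.9-fold higher (114 ± 0.588 against 2.57 ± 1.57 CPM, mean ± SD, n = 2 libraries). Gad2 (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874, + strand), which makes GABA, was 22.0-fold higher (1070 ± 33.3 against 47.0 ± 6.24 CPM). In excitatory neurons Nrn1 (ENSMUSG00000039114, chromosome 13, 36725361 to 36735131, - strand), which encodes the neurite growth factor neuritin, was 41.4-fold higher (136 ± 16.3 against 3.38 ± 0.307 CPM). Ebf3 (ENSMUSG00000010476, chromosome 7, 137193673 to 137314445, - strand), a transcription factor, was 32.8-fold higher. After each gene stand the log2 fold change and a standard error (n = 2 libraries per arm). This error was computed back from the fold change and edgeR's F statistic, which uses spread shared over genes. It does not show how far the 2 libraries lay apart. Where a single library's fold differed from the fitted one by more than 1.5 times, the log2 fold changes of the library labelled male and the library labelled female follow. Their UMIs in each arm follow instead where an arm had 3 or fewer. In each comparison, the highest and lowest genes are those with at least 50 CPM in the higher group and 1 direction in both libraries. The 8 highest in inhibitory neurons were Dlx1 (5.39 ± 0.13, 6.22 and 4.92), Gad2 (4.46 ± 0.05), the neurokinin B precursor Tac2 (3.67 ± 0.09), the homeobox genes Meis2 (3.46 ± 0.09) and Prox1 (3.27 ± 0.12), Ecel1 (3.08 ± 0.07), galanin, Gal (2.99 ± 0.07), and neurotensin, Nts (2.86 ± 0.07). The 8 lowest were Nrn1 (-5.37 ± 0.11), Pmch (-5.13 ± 0.04), Ebf3 (-5.03 ± 0.15), Hcrt (-4.82 ± 0.04), the neurexophilin gene Nxph4 (-4.52 ± 0.13), thyrotropin-releasing hormone, Trh (-4.40 ± 0.08), the synapse organiser Cbln1 (-4.31 ± 0.07) and the peptide PACAP, Adcyap1 (-4.27 ± 0.14, -5.12 and -3.64). The differences in Pmch and Hcrt lay in the Hcrt-high and Pmch-high neurons, which were sorted by these 2 genes. Without these neurons the log2 fold changes were -0.03 and -0.13 and neither was called, an outcome that the sorting largely fixes. The largest adjusted p-value of the 16 genes was 2.86e-42 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

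**Figure D3:**
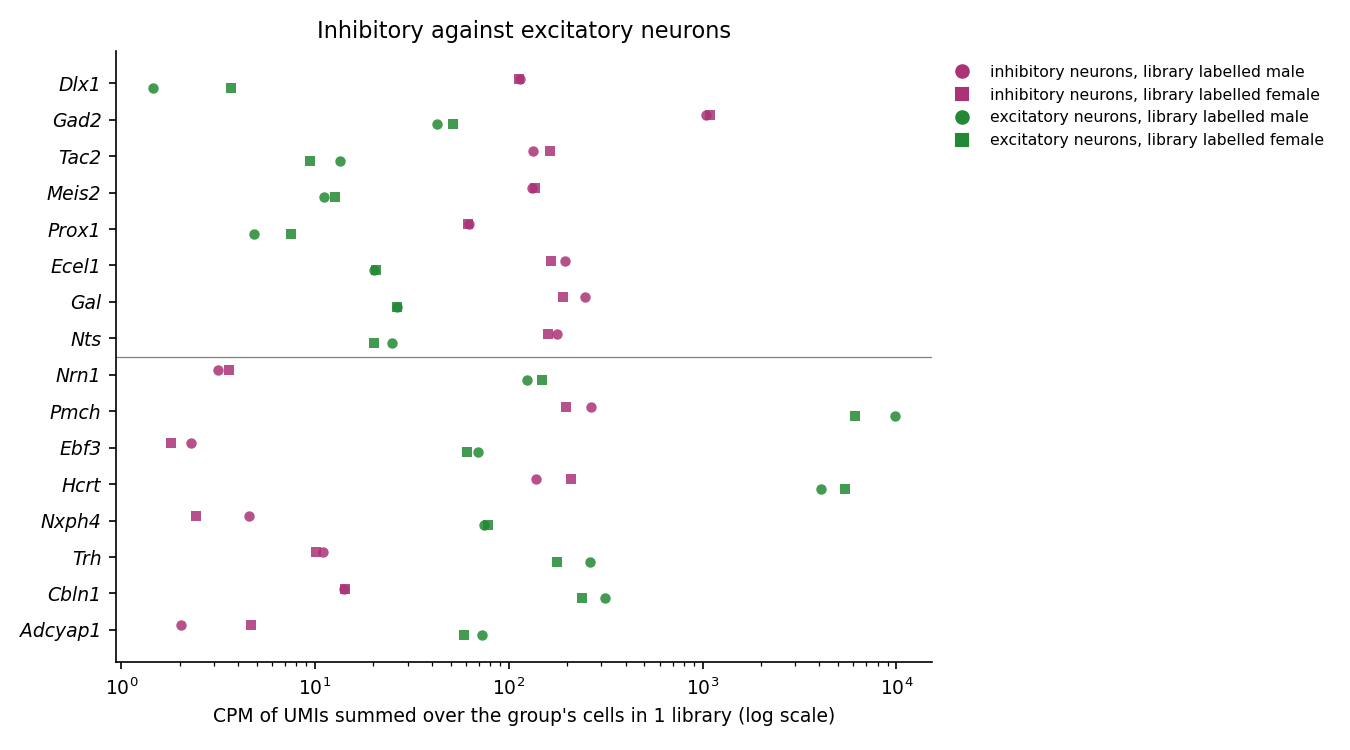
CPM of the 8 highest and 8 lowest genes at 50 CPM or more between inhibitory and excitatory neurons, on a log axis, with 1 point per library and group. By the rule that chose them, in both libraries the 8 inhibitory genes were higher in inhibitory neurons and the 8 excitatory genes in excitatory neurons.

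Grouped by the lists fixed beforehand, the GABA genes went with the gate. Of the 6 genes of GABA synthesis and transport, 5 were higher and 1 was lower (5 and 1 adjusted over the list alone, 4 and 0 by DESeq2). Among them were Gad1 (2.14 ± 0.04) and Abat (0.38 ± 0.04) after Gad2. Of the 5 glutamate genes, 0 were higher and 1 was lower (0 and 1 adjusted over the list alone, 0 and 1 by DESeq2): the transporter Slc17a8 (-3.01 ± 0.31), while Slc1a2 (0.12 ± 0.05) did not pass the test. Among 7 acetylcholine and monoamine genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone, 3 and 0 by DESeq2), led by the vesicular transporter Slc18a2 (3.51 ± 0.16), Hdc (2.43 ± 0.39, 4.76 and -1.35), which makes histamine, and Th (2.12 ± 0.13), which makes L-DOPA, against the choline transporter Slc5a7 (-1.44 ± 0.31). Without Hcrt-high and Pmch-high neurons Slc5a7 turned to 0.11, and 4 of 6 were higher and 0 lower. The neuropeptide list also holds the synapse organiser Cbln1 and the neurotrophin gene Bdnf. Of its 27 genes, 6 were higher and 16 lower (6 and 17 adjusted over the list alone, 6 and 13 by DESeq2), the lowest with more than 3 UMIs being Qrfp (-5.93 ± 0.30, 5 against 180 and 1 against 131 UMIs) and oxytocin, Oxt (-5.24 ± 0.15, -0.96 and -5.75). One neuron of the library labelled female held 4895 of the 5147 Oxt UMIs of that library's neurons. The peptides Tac1 (-0.10 ± 0.05) and Npy (0.10 ± 0.14) did not pass. Inhibitory lineage factors were mostly higher in inhibitory neurons: of 19, 15 were higher and 2 lower (15 and 2 adjusted over the list alone, 14 and 2 by DESeq2), such as Dlx6os1 (5.97 ± 0.34, 141 against 0 and 185 against 4 UMIs) and Lhx8 (at least 11.7-fold). Excitatory lineage factors were mostly lower: of 25, 4 were higher and 21 lower (4 and 21 adjusted over the list alone, 0 and 14 by DESeq2), such as Lhx9 (-6.53 ± 0.25, 1 against 270 and 6 against 274 UMIs) and Barhl1 (at least 12.8-fold). Folds given as "at least" are against a floor of 3 counts over the group, and folds with a range are ratios with 1 to 3 UMIs in the lower group and their counting interval. Among the members of each list, examples follow the order of size and were picked after the values were seen.

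Some genes of receptors, channels and calcium-binding proteins were also called by edgeR, and fewer by DESeq2. Of the 31 peptide and hormone receptors, 11 were higher and 6 lower (12 and 6 adjusted over the list alone, 1 and 2 by DESeq2). The ghrelin receptor Ghsr (1.72 ± 0.56, 15 against 2 and 14 against 5 UMIs) and Npy5r (1.34 ± 0.23) were higher, and the neurokinin B receptor Tacr3 (-2.45 ± 0.10, -2.88 and -1.84) and the receptor Trhr (-1.49 ± 0.10) lower. With cells thinned to 3000 UMIs 1 of 26 receptors was higher and 3 were lower, and without Hcrt-high and Pmch-high neurons 6 of 31 were higher and 5 lower. In the latter Ghsr was at 1.55 and not called, and Tacr3 turned to 0.40. Of the 7 calcium-binding proteins, 0 were higher and 6 lower (0 and 6 adjusted over the list alone, 0 and 5 by DESeq2), led by Calb1 (-1.44 ± 0.05), Pvalb (-1.32 ± 0.13), Calb2 (-1.15 ± 0.05) and Necab2 (-1.05 ± 0.09). Ion channel genes went both ways: of 17, 7 were higher and 5 lower (7 and 5 adjusted over the list alone, 6 and 2 by DESeq2). Among them, the calcium channel subunit Cacna2d1 (-3.09 ± 0.06) was lower and Cacna2d3 (1.05 ± 0.10) and Cacna2d2 (0.95 ± 0.05) were higher. Of the 25 GABA and glutamate receptor genes, 8 were higher and 3 lower (8 and 3 adjusted over the list alone, 2 and 1 by DESeq2). Among them, Grik3 (2.23 ± 0.10) and Gabre (0.92 ± 0.08) were higher and Gabra2 (-0.84 ± 0.05) was lower. Among the companions of Hcrt neurons, 0 were higher and 7 lower (0 and 8 adjusted over the list alone, 0 and 7 by DESeq2) of 8, with Rfx4 (-4.49 ± 0.17) and Nptx2 (-4.17 ± 0.11) lower and Hcrtr2 (-0.32 ± 0.16) not called. Among those of Pmch neurons, 2 were higher and 4 lower (2 and 4 adjusted over the list alone, 2 and 3 by DESeq2) of 7, with Otx1 (-6.15 ± 0.34, 1 against 144 and 3 against 104 UMIs) lower and Mchr1 (-0.23 ± 0.18) not called. Without Hcrt-high and Pmch-high neurons 3 of 6 were higher and 0 lower, and Cartpt was then called higher, as it was with cells thinned to 3000 UMIs.

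Early response and stress genes that passed the test over all genes were lower in inhibitory neurons. Of the 17 early response genes, which rise within minutes of neuronal activation, 0 were higher and 7 lower (1 and 7 adjusted over the list alone, 0 and 1 by DESeq2), including Nr4a3 (-1.49 ± 0.19, -0.39 and -1.69), Fos (-1.01 ± 0.09) and Fosl2 (-0.71 ± 0.16). Of the 11 heat shock and stress genes, 0 were higher and 5 lower (1 and 6 adjusted over the list alone, 0 and 2 by DESeq2), including Gadd45g (-0.52 ± 0.09) and Ddit4 (-0.39 ± 0.11). Without Hcrt-high and Pmch-high neurons these counts were 0 higher and 2 lower in each of these 2 lists. The log2 fold changes of Fos and Nr4a3 were -0.21 and -0.37 and not called, and that of Fosl2 turned to 0.07. Of the 11 mitochondrial transcripts, 4 were higher and 0 lower (4 and 0 adjusted over the list alone, 0 and 0 by DESeq2), including mt-Nd4l (0.15 ± 0.04). Without Hcrt-high and Pmch-high neurons 9 of 11 were higher and with cells thinned to 3000 UMIs 6 of 11, mt-Nd4l in neither. Of the 9 myelin genes, which belong to oligodendrocytes, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, 0 and 0 by DESeq2). Among them, Mbp (0.14 ± 0.03) was higher and Mog (-0.52 ± 0.20) was lower, but neither was called without Hcrt-high and Pmch-high neurons or with thinned cells. None of the 10 sex-linked and 4 hemoglobin genes was called by edgeR, over all genes or over the list alone, or by DESeq2, and 1 and 0 had an unadjusted p under 0.05.

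In total, edgeR's quasi-likelihood test called 3183 of 13225 genes at an adjusted p under 0.05, 1462 higher in inhibitory and 1721 higher in excitatory neurons, and 139 and 413 of them by at least 2-fold. DESeq2 called 556, 185 and 371, and of the genes named here it did not call Hdc, Slc5a7, Oxt, Npy5r, Ghsr, Lhx8, Barhl1, Nr4a3, Fos, Fosl2, Gadd45g, Ddit4, mt-Nd4l, Mbp and Mog. Each arm held the same 2 libraries, which left 1 residual degree of freedom. With the library as a block, p-values rest on how far group differences varied between these 2 pools of littermates, which also differ in sex. That variation was mostly shared over genes, with 92.7 prior against 1 residual degree of freedom. A gene could therefore pass although its own 2 libraries disagreed, as Hdc did. The p-values do not measure the spread between animals. Without the Hcrt-high and Pmch-high neurons edgeR called 1819 genes, 1473 of which were among the 3183, and with cells thinned to 3000 UMIs 741.

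Among the genes that differed most between Hcrt-high and other excitatory neurons were transcription factors, the dynorphin precursor and secreted proteins. Rfx4 (ENSMUSG00000020037, chromosome 10, 84756062 to 84906538, + strand), a transcription factor, was 72.5-fold higher (263 ± 27.9 against 4.39 ± 1.60 CPM, mean ± SD, n = 2 libraries). Pdyn (ENSMUSG00000027400, chromosome 2, 129686565 to 129699844, - strand), the dynorphin precursor, was 27.5-fold higher (1092 ± 8.88 against 47.2 ± 8.14 CPM). C1ql3 (ENSMUSG00000049630, chromosome 2, 13003457 to 13011806, - strand), a secreted synaptic protein, was 46.5-fold higher (1159 ± 16.6 against 29.6 ± 0.297 CPM). Trh (ENSMUSG00000005892, chromosome 6, 92242061 to 92244650, - strand) stood at 2.43 ± 0.314 against 297 ± 94.9 CPM. The 8 highest genes were Rfx4 (6.18 ± 0.16, 5.44 and 6.40), the transcription factor Creb3l1 (6.12 ± 0.25), Thbs2 (6.05 ± 0.28, 5.31 and 6.05), the hyaluronan receptor Cd44 (5.96 ± 0.29, 68 against 1 and 82 against 11 UMIs), C1ql3 (5.54 ± 0.14), Pdyn (4.78 ± 0.13), the prohormone convertase Pcsk1 (4.67 ± 0.13) and the LIM homeobox gene Lhx9 (4.57 ± 0.14). The 8 lowest were Trh (-6.64 ± 0.26), Cbln4 (58.9-fold, 20.1 to 286), Tmem163 (-5.51 ± 0.33), Nrn1 (-5.40 ± 0.25), the homeobox gene Otp (-5.24 ± 0.28, 1 against 611 and 6 against 756 UMIs), Nxph4 (-4.91 ± 0.29), Ebf3 (-4.90 ± 0.31) and Adcyap1 (-4.88 ± 0.31). The largest of their adjusted p-values was 2.94e-48 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The libraries' own log2 fold changes are on the CPM scale, on which the median of all genes lay 0.24 below that of the fitted values.

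Of the 8 companions of Hcrt neurons, 6 were higher and 0 lower (6 and 0 adjusted over the list alone, 6 and 0 by DESeq2), among them the granin Scg2 (4.44 ± 0.18), while Hcrtr2 (-0.51 ± 0.31, -0.27 and -1.17) and Qrfp (0.02 ± 0.23) did not pass. The other excitatory neurons pool many clusters, so genes that mark one of those clusters can be lower in Hcrt-high neurons for that reason alone. Hcrt-high neurons were also deeper, with medians of 16381 and 18305 against 7853 and 8097 UMIs, so free RNA would be a smaller share of their UMIs. The counts of lower genes in the lists below were not set apart from either, and no test with thinned cells was run for the peptide groups. Most other peptides were lower: of 23 neuropeptides, 4 were higher and 16 lower (4 and 17 adjusted over the list alone, 2 and 9 by DESeq2), and Npvf (-0.59 ± 0.27, 30 against 28 and 1 against 227 UMIs) was not called. The fold change of Oxt (-5.67 ± 0.23, 2 against 75 and 17 against 4960 UMIs) rested mainly on 1 neuron of the library labelled female, which held 4895 of these UMIs, and without it that library had 12.5 against 11.2 CPM. Of the 29 peptide and hormone receptors, 6 were higher and 16 lower (7 and 16 adjusted over the list alone, 5 and 6 by DESeq2), led by the calcitonin receptor Calcr (-3.81 ± 0.28, 3 against 322 and 8 against 471 UMIs). Lineage factors were nearly all lower: of 8 inhibitory ones, 0 were higher and 7 lower (0 and 7 adjusted over the list alone, 0 and 4 by DESeq2). Among them were Nkx2-1 (-3.96 ± 0.34) and Meis2 (-2.67 ± 0.50, 1 against 73 and 4 against 92 UMIs). Of 20 excitatory ones, 1 was higher and 18 lower (1 and 19 adjusted over the list alone, 1 and 12 by DESeq2). Among them were Foxb1 (at least 12.8-fold) and Ebf2 (at least 12.1-fold). GABA and glutamate receptor genes were mostly lower too: of 25, 4 were higher and 14 lower (4 and 14 adjusted over the list alone, 3 and 11 by DESeq2). Among them were Grin2a (-3.44 ± 0.28, 9 against 304 and 3 against 369 UMIs), Grik3 (-2.73 ± 0.45, 4 against 85 and 2 against 121 UMIs) and Gabra5 (-2.60 ± 0.24). Of the 17 channel genes, 4 were higher and 11 lower (4 and 11 adjusted over the list alone, 2 and 7 by DESeq2). Among them were Kcnab1 (-2.90 ± 0.35), Kcnq3 (-1.97 ± 0.20) and Scn1a (-1.84 ± 0.16). Of the 7 calcium-binding proteins, 4 were higher and 3 lower (4 and 3 adjusted over the list alone, 3 and 3 by DESeq2). Among them, Necab1 (-3.37 ± 0.28, 3 against 331 and 10 against 361 UMIs), Pvalb (-3.33 ± 0.37, 2 against 203 and 5 against 162 UMIs) and Hpcal1 (-3.10 ± 0.19) were lower and Ncald (2.26 ± 0.12) was higher. Of the 6 GABA genes, 3 were higher and 2 lower (3 and 2 adjusted over the list alone, 1 and 1 by DESeq2). Among them, Gad1 (-0.49 ± 0.14) was lower and Slc6a11 (0.68 ± 0.12) was higher. Of the 5 glutamate genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone, 1 and 0 by DESeq2). Among them, Slc1a1 (-1.05 ± 0.18, -2.20 and -0.76) was lower. Of the 5 acetylcholine and monoamine genes, 2 were higher and 1 was lower (2 and 2 adjusted over the list alone, 1 and 0 by DESeq2). Among them, the dopamine transporter Slc6a3 (97.0-fold, 25.3 to 825) and Ddc (1.19 ± 0.21, 0.58 and 1.23) were higher. Among companions of Pmch neurons, 1 was higher and 3 lower (1 and 3 adjusted over the list alone, 0 and 1 by DESeq2) of 6, with Tacr3 (-2.61 ± 0.57) and Cartpt (-1.74 ± 0.18, -2.58 and -1.53) lower and Nucb2 (1.11 ± 0.22) higher.

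More early response genes were called higher than lower in Hcrt-high neurons: of 17, 9 were higher and 2 lower (10 and 2 adjusted over the list alone, 5 and 0 by DESeq2), the higher ones including Nr4a3 (3.39 ± 0.21), Fos (2.90 ± 0.11, 1.84 and 3.24), Fosl2 (2.86 ± 0.20) and Nr4a1 (2.07 ± 0.22, 1.01 and 2.10). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, + strand) stood at 317 ± 187 against 49.6 ± 2.96 CPM. Of the 10 heat shock and stress genes, 5 were higher and 1 was lower (5 and 1 adjusted over the list alone, 4 and 0 by DESeq2). Among them, Hspa5 (1.0 ± 0.10) and Hspa8 (0.81 ± 0.12) were higher and Ddit4 (-0.71 ± 0.24, -0.28 and -1.53) was lower. Of the 9 sex-linked genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, 1 and 0 by DESeq2): Eif2s3x (0.56 ± 0.11), Ddx3x (0.32 ± 0.11) and Ddx3y. With no UMI in the library labelled male, Ddx3y (324 against 994 UMIs in the other) had no replicate, and its call is not read as a difference. Of the 11 mitochondrial transcripts, 2 were higher and 0 lower (1 and 0 adjusted over the list alone, 5 and 0 by DESeq2): mt-Co1 (0.64 ± 0.18) and mt-Co2 (0.42 ± 0.17). Of the 9 myelin genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone, 0 and 1 by DESeq2). Among them, Mal (0.63 ± 0.26) and Cnp (0.56 ± 0.19) were higher and Mbp (-0.43 ± 0.12) and Mobp (-0.31 ± 0.11) were lower. None of the 3 hemoglobin genes was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. In total edgeR called 4901 of 11828 genes, 2535 higher and 2366 lower (807 and 1208 by at least 2-fold). DESeq2 called 1620, 937 and 683, and did not call Gad1, Slc1a1, Ddc, Tacr3, Nucb2, Ddit4, Ddx3y, Ddx3x, Mal, Cnp and Mobp.

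Summed over the group, Pmch-high neurons held more transcripts of the companion peptide CART and of the neurokinin B receptor, though not every cell held them. Cartpt (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091, - strand), the CART precursor, was 86.9-fold higher than in other excitatory neurons (6183 ± 1464 against 85.1 ± 10.8 CPM, mean ± SD, n = 2 libraries). Tacr3 (ENSMUSG00000028172, chromosome 3, 134829007 to 134934579, + strand), the receptor, was 64.3-fold higher (641 ± 52.9 against 12.1 ± 4.53 CPM). The zinc finger gene Zic1 (ENSMUSG00000032368, chromosome 9, 91358058 to 91365810, - strand) was 23.3-fold higher (429 ± 7.20 against 21.9 ± 7.05 CPM). The 8 highest genes were Parpbp (6.69 ± 0.28, 151 against 10 and 118 against 3 UMIs), Cartpt (6.44 ± 0.12, 5.79 and 6.54), the homeobox gene Otx1 (6.12 ± 0.22, 6.44 and 5.41), Tacr3 (6.01 ± 0.12), Chodl (5.23 ± 0.14), S100a11 (4.94 ± 0.27, 5.23 and 4.27), the elongation factor Ell2 (4.61 ± 0.13) and Zic1 (4.54 ± 0.12). Parpbp (ENSMUSG00000035365, chromosome 10, 88091432 to 88146941, - strand) overlaps Pmch (ENSMUSG00000035383, chromosome 10, 88091072 to 88092375, + strand) on the opposite strand. A use of strand in counting is not given in the sources used here, so its UMIs cannot be separated from those of Pmch and its value is uncertain. The 8 lowest were Trh (-5.84 ± 0.23, -6.86 and -5.02), Otp (-5.70 ± 0.26), Calcr (-5.20 ± 0.34, 1 against 322 and 3 against 471 UMIs), the calcium-binding gene Necab1 (-5.05 ± 0.36, 1 against 331 and 3 against 361 UMIs), Ebf3 (-4.92 ± 0.28), Mdga1 (-4.75 ± 0.29), neurogranin, Nrgn (-4.73 ± 0.24, -5.46 and -4.11), and Nxph4 (-4.71 ± 0.29, 2 against 504 and 6 against 586 UMIs). The largest of their adjusted p-values was 2.46e-07 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median of all genes on the CPM scale lay 0.25 below that of the fitted values.

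Of the 7 companions of Pmch neurons, 5 were higher and 0 lower (5 and 1 adjusted over the list alone, 5 and 0 by DESeq2), including Nucb2 (3.07 ± 0.16), while Mchr1 (-0.23 ± 0.35, -0.19 and -0.85) and Gad2 (-0.48 ± 0.20, -1.18 and -0.38) did not pass. Of the 6 GABA genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone, 2 and 1 by DESeq2). Among them, Gad1 (2.85 ± 0.08) and Slc6a11 (0.76 ± 0.11) were higher and Aldh5a1 (-0.70 ± 0.15) was lower, with Gad1 at 540.0 ± 16.4 against 90.2 ± 5.34 CPM. The choline transporter Slc5a7 (4.45 ± 0.34) was higher (80 against 19 UMIs), and among 5 acetylcholine and monoamine genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone, 1 and 0 by DESeq2). None of 5 glutamate genes was called by edgeR, over all genes or over the list alone, or by DESeq2, and 1 had an unadjusted p under 0.05. All tested companions of Hcrt neurons were lower: of 8, 0 were higher and 8 lower (0 and 8 adjusted over the list alone, 0 and 6 by DESeq2). Among them was Pdyn (-3.99 ± 0.33). As for Hcrt-high neurons, the other excitatory neurons pool many clusters and were shallower, and counts of lower genes were not set apart from either. Of the 24 neuropeptides, 3 were higher and 16 lower (3 and 16 adjusted over the list alone, 3 and 13 by DESeq2). Of the 29 receptors, 5 were higher and 15 lower (5 and 17 adjusted over the list alone, 3 and 5 by DESeq2). Inhibitory lineage factors went both ways: of 8, 2 were higher and 3 lower (2 and 4 adjusted over the list alone, 1 and 1 by DESeq2). Among them, Nkx2-1 (1.81 ± 0.12) was higher and Meis2 (-2.39 ± 0.44) and Isl1 (-0.74 ± 0.19) were lower. Excitatory ones that passed the test were lower except Zic1: of 20, 1 was higher and 18 lower (1 and 18 adjusted over the list alone, 1 and 6 by DESeq2). Among them was Foxb1 (at least 12.9-fold). Of the 7 calcium-binding proteins, 3 were higher and 4 lower (3 and 4 adjusted over the list alone, 1 and 3 by DESeq2). Among them, Pvalb (-3.60 ± 0.40, 2 against 203 and 4 against 162 UMIs) and Calb1 (-0.83 ± 0.10) were lower and Hpcal1 (0.75 ± 0.11) was higher. Of the 17 channel genes, 4 were higher and 6 lower (5 and 7 adjusted over the list alone, 3 and 4 by DESeq2). Among them, Scn1a (-1.80 ± 0.14) and Kcnj3 (-1.78 ± 0.22) were lower and Kcnip4 (1.77 ± 0.09) was higher. Of the 25 GABA and glutamate receptor genes, 8 were higher and 9 lower (8 and 9 adjusted over the list alone, 6 and 6 by DESeq2). Among them, Gabre (-3.07 ± 0.35, 3 against 180 and 6 against 214 UMIs) and Gabrq (-1.65 ± 0.15) were lower and Gabrg1 (2.22 ± 0.13, 2.25 and 1.63) and Gabra2 (1.55 ± 0.09) were higher.

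By edgeR, but not by DESeq2, most early response genes were lower in Pmch-high than in other excitatory neurons: of 16, 1 was higher and 9 lower (1 and 10 adjusted over the list alone, 0 and 1 by DESeq2), with Nr4a2 (at least 4.65-fold), Fosl2 (-1.88 ± 0.56, 3 against 24 and 2 against 84 UMIs), Egr1 (-1.76 ± 0.27, -1.32 and -2.98) and Btg2 (-1.75 ± 0.30, -1.71 and -2.35). Of the 10 heat shock and stress genes, 3 were higher and 3 lower (3 and 3 adjusted over the list alone, 2 and 0 by DESeq2). Among them, Hspa5 (0.91 ± 0.08) and Gadd45g (0.69 ± 0.15) were higher. By edgeR most myelin genes were higher in this group: of 9, 7 were higher and 1 was lower (7 and 1 adjusted over the list alone, 2 and 0 by DESeq2). Among them, Cldn11 (1.48 ± 0.25, 1.63 and 0.60), Mog (1.29 ± 0.39, 1.73 and 0.02) and Trf (1.21 ± 0.37) were higher. Without the neurons that had 1% or more of their UMIs in this list, a limit chosen after the values were seen, 2 were higher and 2 lower. One Pmch-high droplet of the library labelled male held 50 of the 95 Cldn11 UMIs and 21 of the 41 Mog UMIs of all Pmch-high neurons. Mbp, named after its value was seen, was lower (-0.27 ± 0.06). Of the 11 mitochondrial transcripts, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, 1 and 0 by DESeq2). Among them, mt-Nd4l (-0.29 ± 0.08) and mt-Co1 (-0.15 ± 0.04) were lower and mt-Nd1 (0.15 ± 0.05) was higher, although on the CPM scale mt-Nd1 was at -0.14 and -0.07. Of the 9 sex-linked genes, 0 were higher and 1 was lower (0 and 0 adjusted over the list alone, 0 and 0 by DESeq2), the 1 being Ddx3y (110 against 994 UMIs in the library labelled female). It again had no replicate, DESeq2 put it at 0.68, and its call is not read as a difference. None of the 4 hemoglobin genes was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. In total edgeR called 4015 of 11802 genes, 2158 higher and 1857 lower (726 and 836 by at least 2-fold). DESeq2 called 1399, 951 and 448, and did not call Aldh5a1, Meis2, Isl1, Nr4a2, Fosl2, Egr1, Gadd45g, Ddx3y, mt-Nd4l, mt-Co1, Mog, Trf and Mbp. The comparisons of Hcrt-high and of Pmch-high neurons share their excitatory arm, so no overlap between them was counted.

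Compared directly, Hcrt-high neurons held more dynorphin precursor and Pmch-high neurons more CART precursor transcripts. Pdyn was 426-fold higher in Hcrt-high neurons (1092 ± 8.88 against 2.46 ± 0.519 CPM, mean ± SD, n = 2 libraries), and Cartpt 301-fold higher in Pmch-high neurons (6183 ± 1464 against 20.8 ± 8.11 CPM). The 8 highest genes in Hcrt-high neurons were the kinase gene Cdkl4 (at least 52.2-fold), which DESeq2 did not call, Rfx4 (661-fold, 118 to 26146), Pdyn (8.74 ± 0.24), Lhx9 (509-fold, 90.9 to 20125), C1ql3 (8.26 ± 0.22), Thbs2 (175-fold, 30.9 to 6932), Igfbp3 (136-fold, 37.4 to 1132) and the receptor Crhr2 (136-fold, 24.1 to 5427). The 8 lowest were Zic1 (533-fold, 147 to 4406), Tacr3 (-8.57 ± 0.25, 3 against 973 and 1 against 641 UMIs), Cartpt (-8.23 ± 0.21), the growth factor Igf1 (-7.23 ± 0.28, 1 against 388 and 3 against 250 UMIs), Otx1 (158-fold, 43.4 to 1311), Parpbp (134-fold, 36.8 to 1113), uncertain through its overlap with Pmch, Adgrf5 (-6.32 ± 0.29, 1 against 243 and 4 against 171 UMIs) and Rspo3 (68.1-fold, 23 to 333). The largest adjusted p-value among them was 3.19e-36 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In total edgeR called 3314 of 9682 genes, 1531 higher in Hcrt-high and 1783 higher in Pmch-high neurons (639 and 843 by at least 2-fold), and DESeq2 862, 407 and 455.

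**Figure D4:**
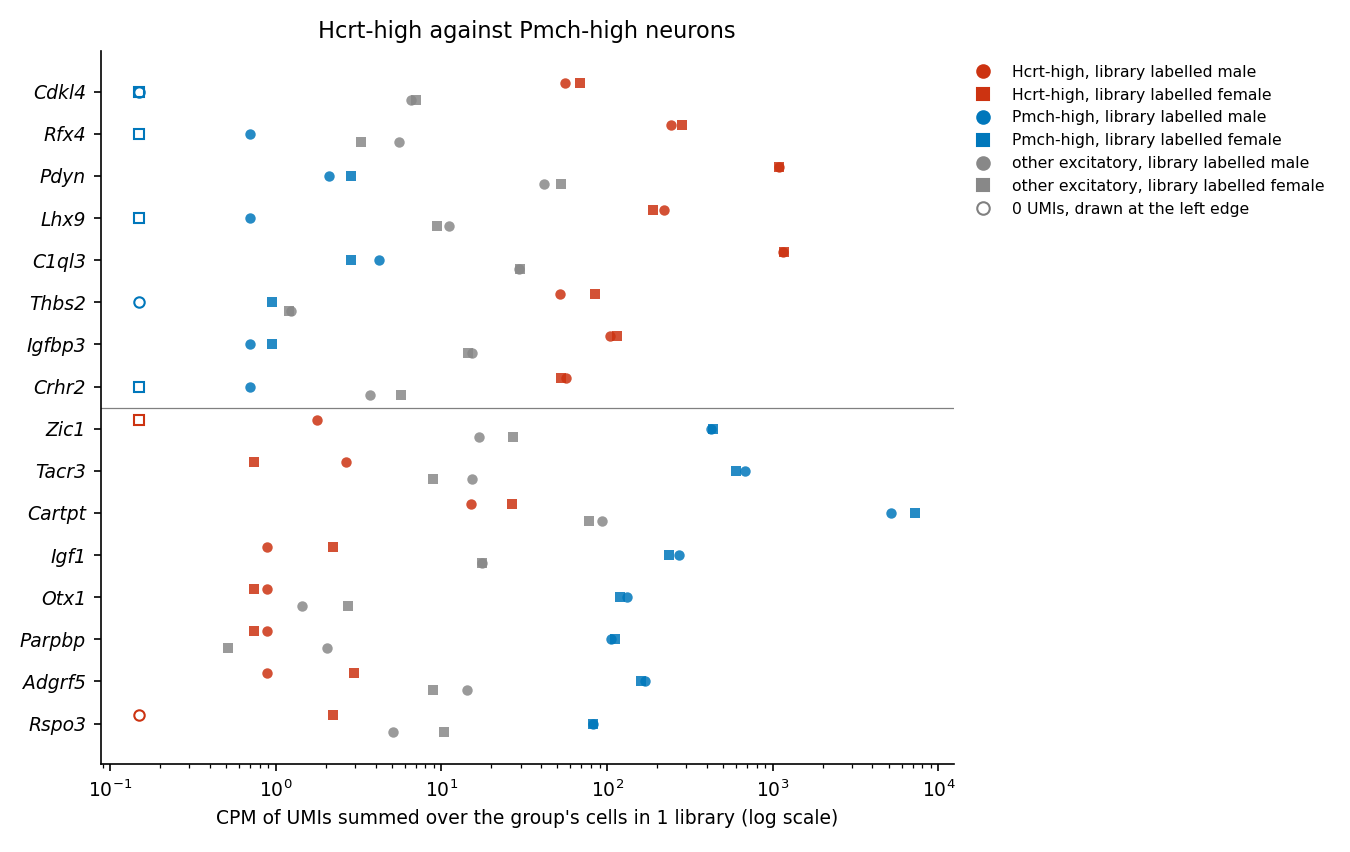
CPM in Hcrt-high, Pmch-high and other excitatory neurons of the 8 highest and 8 lowest genes at 50 CPM or more between Hcrt-high and Pmch-high neurons, on a log axis, with 1 point per library and group and open points at the left edge for 0 UMIs. By the rule that chose them, in both libraries the first 8 were higher in Hcrt-high neurons and the last 8 in Pmch-high neurons.

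By edgeR most early response genes were higher in Hcrt-high than in Pmch-high neurons: of 13, 10 were higher and 0 lower (11 and 0 adjusted over the list alone, 6 and 0 by DESeq2). Among them were Nr4a2 (at least 9.03-fold), Nr4a3 (80.7-fold, 22.0 to 672), Fosl2 (4.76 ± 0.38) and Fos (4.00 ± 0.17, 209 against 42 and 611 against 3 UMIs). All tested companions of Hcrt neurons were higher: of 8, which include the sorting gene Slc17a6, 8 were higher and 0 lower (8 and 0 adjusted over the list alone, 8 and 0 by DESeq2). Of the 8 companions of Pmch neurons, 2 were higher and 5 lower (2 and 5 adjusted over the list alone, 1 and 5 by DESeq2), the higher ones being Slc17a6 and Gad2 (0.55 ± 0.21, 1.43 and -0.16). Of the 6 GABA genes, 2 were higher and 1 was lower (2 and 1 adjusted over the list alone, 0 and 1 by DESeq2). Among them were Gad1 (-3.35 ± 0.14) and Aldh5a1 (1.16 ± 0.18). Of the 4 glutamate genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone, 0 and 0 by DESeq2). Among them, Slc1a1 (-1.25 ± 0.20, -2.21 and -0.51) was lower. Of the 4 acetylcholine and monoamine genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone, 1 and 1 by DESeq2). Among them, Slc6a3 (22.6-fold, 5.89 to 192) and Ddc (0.76 ± 0.27) were higher and Slc5a7 (79.8-fold, 13.9 to 3189) and Th (-1.43 ± 0.57) were lower. Of the 14 neuropeptides, 5 were higher and 3 lower (6 and 3 adjusted over the list alone, 4 and 1 by DESeq2). Among them, Qrfp (52.2-fold, 8.96 to 2099) was higher and Pnoc (-3.17 ± 0.40, 1 against 64 and 8 against 23 UMIs) was lower. Of the 15 receptors, 6 were higher and 4 lower (6 and 5 adjusted over the list alone, 5 and 4 by DESeq2). Among them, Avpr1a (42.8-fold, 14.3 to 210.3) was higher and Oxtr (111-fold, 19.5 to 4410) was lower. Of the 4 inhibitory lineage factors, 0 were higher and 3 lower (0 and 3 adjusted over the list alone, 0 and 2 by DESeq2). Among them were Nkx2-1 (-5.73 ± 0.28, 2 against 246 and 5 against 143 UMIs) and Nr2f2 (-2.16 ± 0.17). Of the 3 excitatory ones, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, 1 and 2 by DESeq2). Among them, Lhx5 (-2.68 ± 0.46, 2 against 30 and 7 against 26 UMIs) was lower. Of the 5 calcium-binding proteins, 4 were higher and 1 was lower (4 and 1 adjusted over the list alone, 4 and 1 by DESeq2). Among them, Calb1 (2.99 ± 0.13) and Ncald (1.92 ± 0.12) were higher and Hpcal1 (-3.87 ± 0.19) was lower.

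Receptors for fast transmitters were mostly lower in Hcrt-high than in Pmch-high neurons: of 23, 4 were higher and 16 lower (4 and 16 adjusted over the list alone, 3 and 9 by DESeq2), with Gabrq (3.40 ± 0.16) among the higher ones. Of the 17 channel genes, 3 were higher and 7 lower (3 and 7 adjusted over the list alone, 0 and 4 by DESeq2). Among them were Kcnip4 (-2.45 ± 0.14) and Kcnab1 (-2.25 ± 0.50). Of the 8 heat shock and stress genes, 3 were higher and 2 lower (3 and 2 adjusted over the list alone, 2 and 0 by DESeq2). Among them were Hsph1 (0.82 ± 0.11) and Ddit4 (-0.94 ± 0.29). Of the 11 mitochondrial transcripts, 2 were higher and 0 lower (1 and 0 adjusted over the list alone, 3 and 0 by DESeq2): mt-Co1 (0.77 ± 0.15) and mt-Co2 (0.36 ± 0.14). Of the 9 sex-linked genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, 0 and 0 by DESeq2). Among them were Ddx3x (0.43 ± 0.12) and, again without a replicate and so not read as different, Ddx3y (324 against 110 UMIs). Of the 9 myelin genes, 0 were higher and 5 lower (0 and 5 adjusted over the list alone, 0 and 0 by DESeq2). Among them were Mog (-2.05 ± 0.52, -2.51 and -1.14) and Mag (-1.16 ± 0.30, -1.67 and -0.27), of which the Pmch-high droplet named above held 21 of 41 and 40 of 79 UMIs of that group. Without the neurons that had 1% or more of their UMIs in this list, 0 of 8 were called. None of the 2 hemoglobin genes was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. DESeq2 did not call Aldh5a1, Gad2, Slc1a1, Th, Ddc, Pnoc, Kcnab1, Ddit4, Mog, Mag, Ddx3y and Ddx3x.

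**Figure D5:**
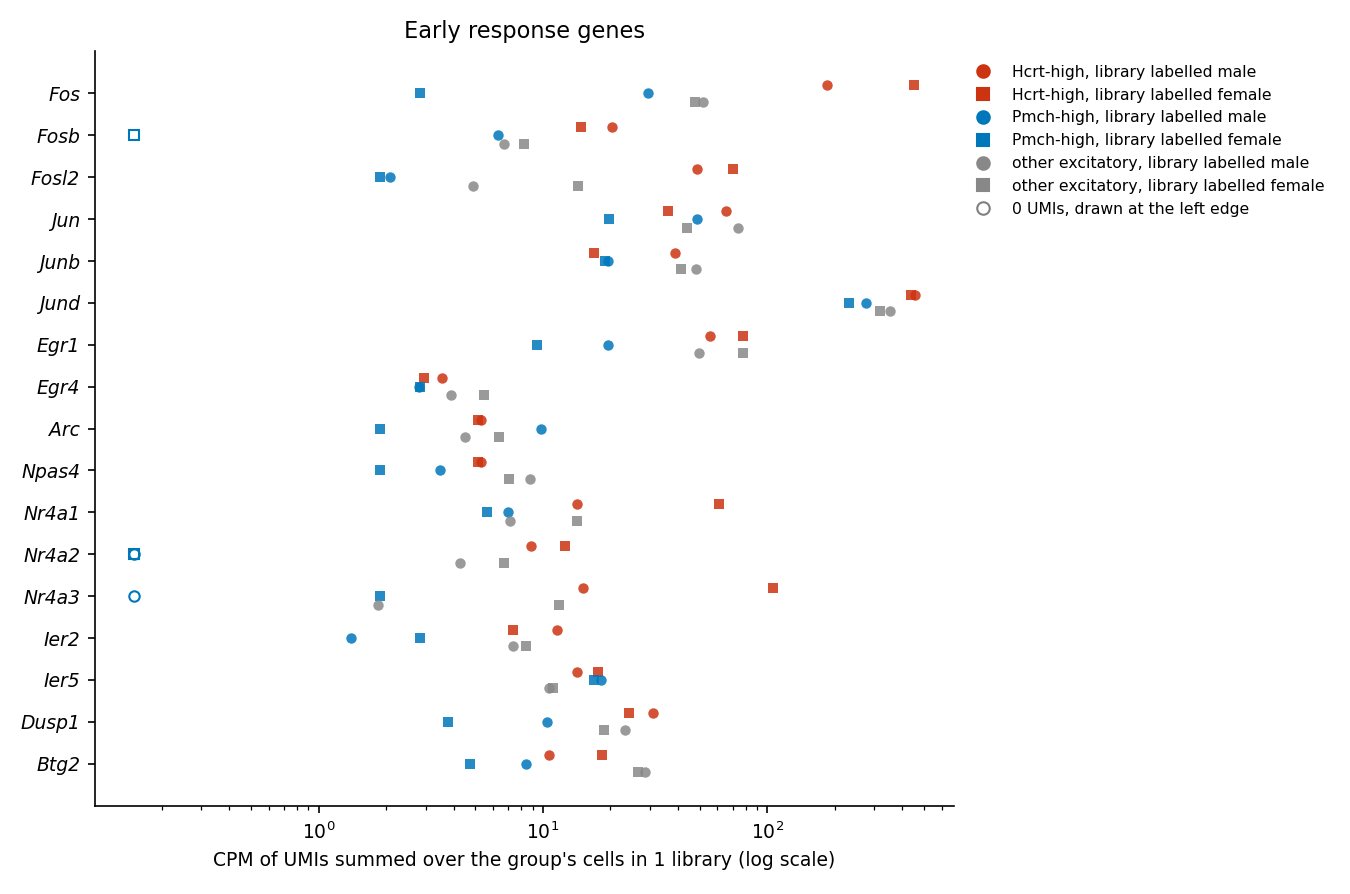
CPM of the early response genes in Hcrt-high, Pmch-high and other excitatory neurons, on a log axis, with 1 point per library and group and open points at the left edge for 0 UMIs. In both libraries Fos was higher in Hcrt-high neurons than in the other groups.

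After thinning every neuron to 3000 UMIs, 10 of 31 genes of the neuropeptide list were more frequent in one group in both libraries. Of these 4 were so in inhibitory and 6 in excitatory neurons, the 6 including Cbln1 and Bdnf, which are not neuropeptides. Crh was so in the library labelled male alone, and the other 20, among them Sst, Npy, Penk, Tac1 and Cartpt, in neither. Gal was found in 22.3% and 21.2% of inhibitory against 4.84% and 4.95% of excitatory neurons, and in 1.77% and 1.75% of mature oligodendrocyte-like cells, which serve as background. Nts, Pnoc and Tac2 were likewise more frequent in inhibitory neurons of both libraries, beyond counting error. Excitatory neurons more often held Cbln1 (33.3% and 24.5% against 3.61% and 4.17%, with 1.77% and 2.10% in oligodendrocyte-like cells) and Adcyap1 (16.3% and 13.7% against 0.64% and 1.30%, with 0.18% and 0.35%), and also Bdnf, Cck, Pdyn and Trh. Unthinned, the shares were 30.2% and 29.6% against 12.8% and 12.2% for Gal, 48.4% and 39.5% against 8.64% and 9.99% for Cbln1, and 27.4% and 25.4% against 1.32% and 2.79% for Adcyap1, and Qrfp joined the excitatory genes. Median depths were 7841 and 8228 UMIs in inhibitory neurons, 8359 and 8368 in excitatory neurons and 4170 and 4643 in oligodendrocyte-like cells, and thinning left out 42 and 31, 29 and 18, and 43 and 22 cells. Hcrt was found in 32.1% and 38.1% of thinned inhibitory neurons and in 30.7% and 37.5% of oligodendrocyte-like cells, and Pmch in 48.0% and 42.5% against 50.2% and 43.1%, so single UMIs of these peptides were at background level.

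When the neurons of each library were clustered on their own, most clusters found a partner in the other library. Inhibitory neurons formed 14 and 17 clusters, of which 13 pairs were each other's best match, with a median correlation of 0.80 over genes (0.62 to 0.92) and 92.8% and 84.8% of cells in matched clusters. Excitatory neurons formed 15 and 17 clusters with 13 such pairs, a median correlation of 0.80 (0.51 to 0.95) and 92.8% and 80.4% of cells. At a finer resolution 18 and 15 pairs were found, and at a coarser one 9 and 10. The shared leading genes named, among inhibitory pairs, 1 with Otp, Six3 and Sst (125 and 64 cells), 1 with Meis2 and Calb2 (79 and 105), 1 with Tac2 and Lamp5 (70 and 72), 1 with Ddc, Slc18a2 and Th (40 and 31) and 1 with Cartpt and Nts (32 and 38). Among excitatory pairs they named 1 with Penk and Gpr101 (146 and 127 cells), 1 with Ebf3 and Nxph4 (56 and 74), 1 with C1ql3, Pdyn and Lhx9 (71 and 50), 1 with Trh and Cbln1 (59 and 36), 1 with Foxb1 and Mef2c (25 and 40) and 1 with Pmch, Cartpt and Tacr3 (40 and 22). The pairs named here were picked from those with several leading genes in common, but the largest inhibitory pair (170 and 189 cells) had 1 of 10 in common, Syt2, and an excitatory pair (74 and 29 cells) also 1, Tac1. These correlations are across genes, which are not independent replicates, and the genes only name the clusters.

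Between the libraries, neurons differed in few genes beyond the sex-linked ones. With 1 library per sex label there is no replicate and no test, and a gene was counted by size alone, at 2-fold or more with at least 50 CPM and 50 UMIs in the higher library. In neuron-like cells 6 of 4241 genes met this. Xist, the vasopressin gene Avp (2.05-fold, 1.96 to 2.13) and Gm26917 (2.05-fold) were higher in the library labelled male, and Ddx3y, Oxt (3.63-fold, 3.41 to 3.87) and the prostaglandin synthase gene Ptgds (2.91-fold, 2.62 to 3.24) in the library labelled female. Avp and Oxt rested on few neurons: 13 and 7 neurons had 10 or more Avp UMIs, and 1 neuron held 73.5% and 95.1% of each library's Oxt UMIs. Ptgds was found in 6.74% and 17.6% of neurons thinned to 3000 UMIs, and in 7.89% (1.66 to 21.4) and 24.2% (11.1 to 42.3) of endothelial-like cells, so a difference in free RNA was not set apart from one in neurons. Of 10865 genes at 5 CPM or more in neurons, 98.5% lay within 1.5-fold and 99.8% within 2-fold, with a median log2 ratio of -0.03.

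Against 10000 random lists matched on expression, in neurons, the median log2 ratio of the library labelled male over the library labelled female stood highest for neuropeptides (0.23, percentile 100), early response genes (0.23, percentile 100) and sex-linked genes (0.25, percentile 100). Of their genes 17 of 25, 8 of 15 and 5 of 9 lay above 0. Pmch neuron companions (0.17, percentile 99.8), calcium-binding proteins (0.15, percentile 99.2) and heat shock and stress genes (0.11, percentile 98.5) followed. Glutamate genes (-0.19, percentile 0.29) and mitochondrial transcripts (-0.06, percentile 0.32) stood lowest. The other lists lay between: GABA and glutamate receptors at percentile 5.99, GABA genes at 7.81, acetylcholine and monoamine genes at 16.9, excitatory lineage factors at 27.1, channels at 40.6, myelin genes at 47.9, Hcrt neuron companions at 57.8, inhibitory lineage factors at 61.3 and peptide and hormone receptors at 81.8. Too few hemoglobin genes reached the 5 CPM needed for this measure. Outside the sex-linked genes, Jun alone met the rule of size in one direction in 3 classes, higher in the library labelled male. Hbb-bs, Hba-a1 and Hba-a2 also met it in 3 classes, but in both directions.

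In other classes, 17 genes met the rule in astrocyte-like, 35 in endothelial-like, 12 in mature oligodendrocyte-like, 46 in newly formed oligodendrocyte-like and 18 in oligodendrocyte precursor-like cells. In mature oligodendrocyte-like cells the kinase gene Sgk1 (8.33-fold, 6.42 to 11), the heat shock gene Dnajb1 (2.62-fold, 1.93 to 3.61) and Mat2a (2.11-fold, 1.90 to 2.33) were higher in the library labelled female, and B2m (3.28-fold, 2.63 to 4.12) in the library labelled male. In oligodendrocyte precursor-like cells Egr1 (23.4-fold, 9.66 to 73.7), Fos (17.4-fold, 7.10 to 55.3) and Jun (5.46-fold, 3.92 to 7.73) were higher in the library labelled male, while in neurons Egr1 and Fos lay the other way (log2 ratios of -0.60 and -0.25). The 2 clusters of newly formed oligodendrocyte-like cells were mixed unequally, with 54 and 57 cells in one and 20 and 47 in the other. Without doublet removal the endothelial-like count was 120. Differences in hemoglobin genes rested on few cells. Of Hba-a1, 1 endothelial-like cell held 628 of the 791 UMIs in the library labelled male, against 37 in the other. In precursor-like cells 4473 of 4660 UMIs in the library labelled female lay in 5 cells, and 845 of 846 in the library labelled male in 1 cell, all of which were named erythrocyte-like at resolution 2.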

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

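The tests of exchanged labels, of mixed pools and of myelin genes, and the split by library of the test for shared droplets, were chosen only after the results they measure were seen. The other tests of Hcrt and Pmch UMIs outside neurons were set before.

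In 7 comparisons of single genes the libraries went opposite ways, and none of these differences between the libraries was tested. Between inhibitory and excitatory neurons, the log2 fold changes in the library labelled male and the library labelled female were 4.76 and -1.35 for Hdc, -0.22 and 0.11 for Tac1, 0.39 and -0.0785 for Npy, and -0.68 and 0.18 for Mchr1. Between Hcrt-high and other excitatory neurons they were -0.48 and 0.10 for Qrfp, and 2.21 and -5.14 for Npvf, whose Hcrt-high arm of the library labelled female held 1 UMI. Between Hcrt-high and Pmch-high neurons they were 1.43 and -0.16 for Gad2. Of these genes Hdc and Gad2 passed edgeR's test over both libraries, and DESeq2 called neither.

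Counts in data that no test used also passed the limit of the fixed rule, which is what a count of 0 allows and which any few UMIs or cells pass. Neurons with UMIs of both Slc32a1 and Slc17a6, which the comparisons left out, numbered 112 in the library labelled male and 146 in the library labelled female. In the library labelled female 30 Xist UMIs were counted. A newly formed oligodendrocyte-like cell held 20 of them and a microglia-like cell 8, both without Y-linked UMIs, and 2 neurons held 1 each beside 4 and 1 Y-linked UMIs.

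The first pattern is that the sex-linked genes ran against both labels. A mixed pool of both sexes in each library is excluded, since the minority kind of barcode made up at most 0.0527% of a library. An exchange of the labels is in line with the values: 77.2% of barcodes of the library labelled female held Y-linked UMIs without Xist, and the library labelled male held none of the Y-linked UMIs. Whether an exchange took place in the deposited labels, in the file names or at the bench was not tested. A true difference by sex between the libraries stays open, untested, and would then run opposite to the labels.

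The second pattern is that, by edgeR, most myelin genes were higher in Pmch-high neurons. Free oligodendrocyte RNA in all droplets was set to raise Mbp with the others, and Mbp was lower, at -0.27. This argues against free RNA as the source of the higher genes. It does not exclude free RNA, which would be a smaller share of UMIs in the deeper Pmch-high neurons. The median share of the list was 0.0943% and 0.116% of UMIs in Pmch-high neurons, against 0.123% and 0.154% in other excitatory neurons. Without the neurons that had 1% or more of their UMIs in the list, 2 genes of the list, Trf and Cnp, were called higher, against 7 with them, but since the list itself chose these neurons, the count leaves open how much of the pattern a few droplets explain. One droplet of the library labelled male held 1372 Pmch UMIs beside 1098 UMIs of the list, and oligodendrocyte RNA in it is a candidate source: Ermn and Opalin, oligodendrocyte markers outside the list, had 22 UMIs there, 1.04 times (0.654 to 1.58) the number its myelin UMIs predict. No biological explanation was tested.

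The third pattern is that Hcrt and Pmch UMIs were found in non-neuronal cells. For free RNA the ratio of Hcrt to Pmch UMIs varied by up to 2.14 times between 5 non-neuronal classes, with intervals that overlapped, above the 1.5 times that it was set to need and below the 3 times that would have excluded it. Free RNA and other sources cannot be told apart here, because the smaller classes held as few as 30 UMIs of a peptide. Droplets shared with a peptide neuron may be the source of many Hcrt UMIs in oligodendrocyte-like cells of the library labelled male. The top 5% of these cells held 56.1% of the class's Hcrt UMIs, a share that counts 5 cells at the peptide gate. As the main source shared droplets are excluded in the library labelled female, where the top 5% held 25.5%. As the source of most UMIs they stay undecided over both libraries together. But over the 5 classes and both libraries, at least 32.7% of cells held Hcrt and at least 52.2% held Pmch, unthinned. This spread argues against shared droplets as the source in most cells with these UMIs. No biological explanation was tested.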

How the results depend on the processing

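Chosen only after the results were seen were the tests without neurons with 1% or more of their UMIs in the myelin list and the test without Hcrt-high and Pmch-high neurons.

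DESeq2 called fewer genes than edgeR in each comparison: 556 against 3183 for inhibitory against excitatory neurons, 1620 against 4901 for Hcrt-high, 1399 against 4015 for Pmch-high and 862 against 3314 for the direct comparison. Of the genes named, 44 of 59, 49 of 60, 39 of 52 and 36 of 49 kept their call or stayed uncalled, and Ddx3y in Pmch-high neurons turned to 0.68. Under each other setting with a test at most 11, 6, 6 and 4 named genes lost their call, and at most 2, 1, 1 and 0 gained one. For inhibitory against excitatory neurons edgeR called 930 genes without the library block, 741 with cells thinned to 3000 UMIs, which keeps fewer UMIs and cells, and 1819 without Hcrt-high and Pmch-high neurons. Otherwise the counts ranged from 2519 to 3321, and for the other comparisons, in the order above, from 3869 to 4897, 3655 to 4535 and 2772 to 3289. In either library alone, which allows no test, genes at 2-fold and 50 CPM numbered 74 to 89, 657 to 679, 551 to 561 and 627 to 630. No pairing by animal was possible because animals were pooled. The library block pairs the groups within each library.

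Some named genes turned between inhibitory and excitatory neurons. Thinning to 3000 UMIs put Slc1a2 at -0.0493, Oxt at 0.24, Tacr3 at 0.0322 and Mog at 0.13. Without Hcrt-high and Pmch-high neurons Slc5a7 was at 0.11, Npy at -0.25, Tacr3 at 0.40 and Fosl2 at 0.0736. Cartpt, called lower in the main test, was called higher under both of these settings. Npy was at -0.21 with a gate of 2 UMIs and at -0.24 without doublet removal, Tac1 at 0.0941 with the stricter cell filter and Hcrtr2 at 0.0823 with groups from clusters. In either library alone Hdc ranged from -1.35 to 4.76.

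In Hcrt-high neurons Qrfp, at 0.02, turned to -0.0359 and -0.52 with peptide gates of 0.1% and 1%, -0.39 with the stricter cell filter, -0.0336 without a filter on low counts and -0.00509 without the block. Npvf turned to 0.60 with the gate of 0.1% and 0.79 with the stricter filter. In Pmch-high neurons Gad2 was at 0.74 with the gate of 0.1% and mt-Co1 at 0.00145 with the stricter filter. In either library alone mt-Nd1 ranged from -0.14 to -0.0750. In the direct comparison Gad2 was at -0.0923 with the gate of 0.1% and from -0.16 to 1.43 in either library alone. For all these genes the cause was not tested. The 8 highest and 8 lowest genes at 50 CPM or more in both libraries were chosen for large changes in 1 direction in both. They could therefore not turn in either library alone and were unlikely to turn elsewhere, and none did. Oxt, at -5.24 and below that limit in the library labelled male, turned.

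Neuron shares rose to 69.5% and 73.5% with the stricter cell filter, which raises the gene limit and lowers the mitochondrial limit together. Without doublet removal these shares fell to 62.6% and 62.9%. With the stricter filter mature oligodendrocyte-like cells fell to 13.7% and 9.62%, and no mural-like cluster was left, and at resolution 0.5 endothelial-like cells rose to 4.58% and 4.21%. The causes were not tested. Genes by the rule of size in neurons numbered 11 at 20 CPM and 22 at 1.5-fold, against 6. Genes that met the rule in one direction in 3 or more classes numbered 2 with the stricter filter and 10 at 1.5-fold, against 4, and the looser limits admit more genes by construction. Under 1 dispersion common to all genes, the self-test recovered 64% to 68% of 2-fold changes in the comparisons of peptide groups. It recovered 90% between inhibitory and excitatory neurons. Depth was not set apart from the spread left after the library block.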

Other observations

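The shares in this part, their genes and the depth of 5000 UMIs were all chosen after the results of the tests were seen.

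After thinning to 5000 UMIs, Fos was found in 51.6% and 69.2% of Hcrt-high neurons, 13.2% and 2.04% of Pmch-high neurons, 11.9% and 10.3% of other excitatory neurons and 4.32% and 2.30% of mature oligodendrocyte-like cells, which serve as background. Nr4a3 was found in 4.69% (95% Clopper-Pearson interval 0.977 to 13.1) and 36.9% (25.3 to 49.8) of Hcrt-high neurons, with intervals that did not overlap between the libraries. Pdyn was found in 96.9% of Hcrt-high neurons in both libraries, and unthinned, over all of them, in 84.1% and 89.3%. Gad1 was found in 88.2% and 85.7% of Pmch-high neurons, against 19.6% and 21.9% of other excitatory neurons and 5.04% and 8.29% of oligodendrocyte-like cells. Thinning left out 18 and 19 Hcrt-high, 17 and 12 Pmch-high, 105 and 75 other excitatory and 470 and 376 oligodendrocyte-like cells, so these shares hold for the deeper cells of each group.

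Within Pmch-high neurons Tacr3 went with Cartpt. After thinning to 5000 UMIs, Cartpt was found in 51.5% and 53.1% and Tacr3 in 63.2% and 59.2% of these neurons. Of the cells with a Cartpt UMI at this depth, 88.6% (31 of 35, 73.3 to 96.8) and 96.2% (25 of 26, 80.4 to 99.9) also held Tacr3, against 36.4% (12 of 33, 20.4 to 54.9) and 17.4% (4 of 23, 4.95 to 38.8) of those without. The intervals did not overlap in either library. In mature oligodendrocyte-like cells at this depth, as background, Cartpt was found in 7.19% and 9.22% and Tacr3 in 0.719% and 0.461%.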
